A study of Homo sapiens with 12 samples.

How the data were processed

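Expression was measured in 12 samples, 3 in each of 4 groups, made of the TC32 and HCT116 cell lines with siNeg or siPRKDC at 20 nM for 48 h. Per the labels, RNA was extracted with a Maxwell 16 kit, amplified as biotinylated cRNA with a TotalPrep-96 kit and hybridized to HumanHT-12 v4 BeadChips. The deposited intensity values are mean probe intensities on a linear scale, neither background-corrected nor normalized, for 47322 probes per array. Array medians ran from 72.4 to 74.6 and maxima from 5202.8 to 6324.6. Per the file headers, a detection p-value accompanies each intensity, taken against the negative control probes of that array. The authors also deposited log2 values, quantile normalized within each cell line separately without background subtraction, in which sorted values of 1 line differed by at most 0.010. The authors name GenomeStudio, R 3.0.2 and lumi, and the versions of GenomeStudio and lumi are not given in the sources used here. In all 12 samples, the deposited log2 value ranked best with the sample's own intensity. No genome build is named with the values, and no coordinates are given.

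The intensities were processed in R 4.3.3 with limma 3.58.1. Background was corrected by neqc, with its mean and SD inferred from the detection p-values, an offset of 16, quantile normalization over all 12 arrays and a log2 scale. A probe was kept if its detection p was below 0.05 on all 3 arrays of at least 1 group. Of all probes, 30113 were paired with 1 gene, 8 with several and 17201 with none. The gene identifiers of 30074 probes were found in the RefSeq table for GRCh38.p14, which was used for names only. The filter kept 16555 probes, of which 13396 had 1 gene. Each gene was represented by its kept probe with the highest mean, leaving 10386 genes, of which 2479 had more than 1 kept probe. Where other probes of a named gene differed in call or sign, this is stated for genes whose text rests on it. A fold against a group in which no array detected the probe is given as at least the fold over the detection floor.

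The 4 groups were fitted together in 1 cell-means model with limma (empirical Bayes with trend and robust options off, 8 residual and 13.5 prior degrees of freedom). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. Counts at an absolute log2 change of at least 1 are also given. The comparisons were siPRKDC against siNeg in TC32 and in HCT116, the difference between these effects (TC32 minus HCT116), and TC32 against HCT116 under siNeg. Genes called in both lines were counted by direction and tested with Fisher's exact test. With 3 samples against 3, the smallest p of an exact permutation test for a single gene is 0.1, so none was used. In simulated data for 10386 genes, independent normal noise with each gene's residual SD over the 4 groups was added to group means. Changes of 0.5, 1 and 2 on the log2 scale were set in TC32 for 67, 67 and 66 genes. Of these, 59.7%, 98.5% and 100% were recovered, and 10 of 182 calls were false. Far fewer genes changed than were called in the real TC32 comparison (42.7%), and real noise may be shared between genes, so these shares need not hold there.

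The model, the threshold, 18 gene lists, the rule for naming genes and 14 alternatives were chosen before the data were examined. The lists were EWS-FLI1 activated targets, EWS-FLI1 repressed targets, non-homologous end joining, homologous recombination and Fanconi anaemia, PIKK kinases and checkpoint, p53 targets, G2/M and mitosis, DNA replication and S phase, interferon response, ATF4 and unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, polyadenylated histone transcripts, NF-kB and inflammatory cytokines, immediate early and MAPK response, ribosome biogenesis, epithelial and colon markers, and Ewing sarcoma, neural and mesenchymal markers. Of 351 list members, 22 had no probe paired to their symbol and 261 were measured. Lists were tested against all other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 18 lists of a comparison. Adjusting over all comparisons together ended no call.

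The rule named PRKDC, EWSR1, FLI1 and NR0B1 in every comparison, but NR0B1 was not among the genes tested. It added the 10 largest rises and falls in each line among called genes whose siPRKDC and siNeg values did not overlap, the 10 largest differences between lines, and the 10 genes with the largest shared change. It further added the 5 genes most different each way under siNeg and up to 4 members per list with the smallest p. ATF4, ZYX, CNN2, HSPA5 and CENPF in TC32, NBN in HCT116, NAP1L1 in TC32 and the structural RNA genes that are not among the largest rises fall outside this rule and were chosen after their values were seen. Symbols without a descriptive name were passed over. Probes without 1 gene were not used, apart from a count. The grouping of structural RNA genes was made after the data were seen.

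The alternatives were an offset of 50, no background correction, median scaling, cyclic loess, the authors' values, no filter on dim probes, detection p below 0.01 on all 12 arrays, the mean of a gene's probes, the trend and robust options, an adjusted p below 0.01, a replicate block, each line fitted alone, the estimated correlation for lists, and leaving out each sample in turn. An analysis without non-polyadenylated RNA probes was added after seeing the data. Replicates correlated at r from 0.990 to 0.994 and no pair of the 66 pairs of arrays was identical. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.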

Results

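Gene expression was measured on Illumina HumanHT-12 v4 BeadChips in 12 samples of human cancer cell lines. TC32 is an Ewing sarcoma line and HCT116 is a colorectal carcinoma line. Each line was transfected with a control siRNA (siNeg) or with an siRNA against PRKDC (siPRKDC), the gene of the DNA-dependent protein kinase catalytic subunit, at 20 nM, and RNA was taken 48 h later. The 4 groups held 3 samples each. Between 15396 and 18153 probes per array gave signal above background, or 32.5% to 38.4%. After filtering, 10386 genes were tested. The number of arrays limited the precision. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

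The first question was how far PRKDC itself fell. PRKDC fell in both lines, and further in HCT116 than in TC32 by its brightest probe. In TC32, its log2 intensity was 6.71 ± 0.17 (SD, n = 3) with siNeg and 5.30 ± 0.32 (SD, n = 3) with siPRKDC. This was a 2.65-fold fall, with a log2 change of -1.41 (SE 0.14, adjusted p = 3.80e-08). In HCT116, the level went from 7.25 ± 0.19 (SD, n = 3) to 4.59 ± 0.17 (SD, n = 3), a 6.31-fold fall with a log2 change of -2.66 (SE 0.14, adjusted p = 4.87e-11). Without background correction the log2 changes were smaller, at -0.75 in TC32 and -1.38 in HCT116, and both were still called. In each line, every siPRKDC sample lay below every siNeg sample. The changes differed between the lines by 1.25 on the log2 scale (SE 0.20, adjusted p = 4.59e-05). With the mean of all kept PRKDC probes, the changes were -1.06 and -1.39, and their difference was 0.33 and was no longer called (adjusted p = 0.0596). The 2 dimmer PRKDC probes fell by 0.86 and by 0.92 in TC32, and by 0.78 and by 0.73 in HCT116, and after siPRKDC they were near background in both lines.

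**Figure D1:**
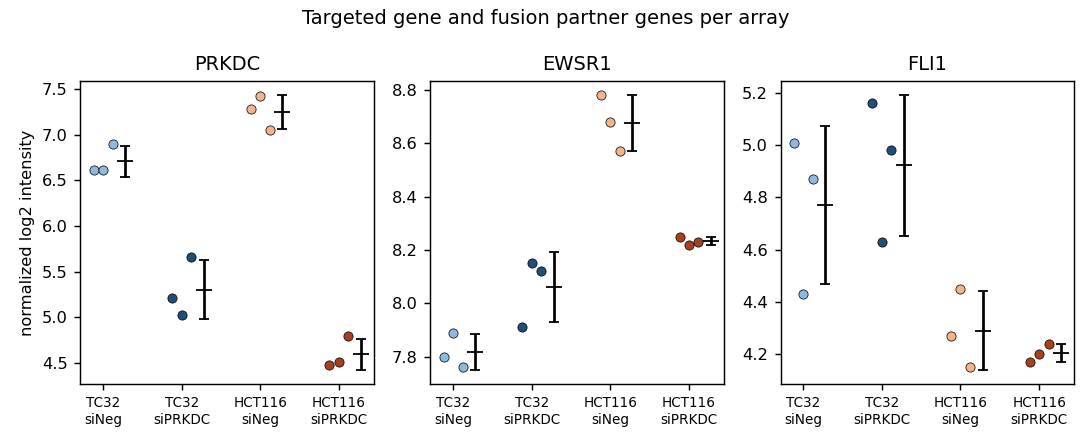
Normalized log2 intensity of the brightest probe of PRKDC, EWSR1 and FLI1 in each of the 12 samples, by cell line and siRNA, with group means and SD. The PRKDC mean went from 6.71 to 5.30 in TC32, and from 7.25 to 4.59 in HCT116.

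EWSR1 and FLI1 are the genes fused in most Ewing sarcomas. Whether their probes read the fused transcript, the normal ones or both was not examined. EWSR1 moved in opposite directions in the lines. It rose by 0.25 on the log2 scale in TC32 (SE 0.09, adjusted p = 0.0404), where its other 2 probes changed by 0.26 and 0.51. This rise was small, and it was no longer called with cyclic loess (adjusted p = 0.0522), with median scaling (0.0570) or with TC32 fitted alone (0.0687). It was also lost without siNeg replicate 1 (adjusted p = 0.0892), siNeg replicate 3 (0.108), siPRKDC replicate 2 (0.146, the highest of any alternative) or siPRKDC replicate 3 (0.120). In HCT116, EWSR1 had a log2 change of -0.44 (SE 0.09, adjusted p = 0.00187), called on the brightest of its 3 probes alone. The difference between the lines was 0.69 (SE 0.13, adjusted p = 4.49e-04). FLI1 did not change detectably in TC32 (log2 change 0.15, adjusted p = 0.403) or HCT116 (-0.09, adjusted p = 0.716), and the difference of 0.24 was not called either (adjusted p = 0.355). However, FLI1 was near background in HCT116 and not far above it in TC32, so there was little room for a fall to be seen.

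The next question was what changed in the Ewing sarcoma line. In TC32, EWS-FLI1 repressed targets and genes of the ATF4 and unfolded protein response fell with siPRKDC. Ribosome biogenesis genes, polyadenylated histone transcripts, and ribosomal and spliceosomal RNAs rose. Of 10386 genes, 4439 changed, 2261 upward and 2178 downward, and 316 changed at least 2-fold (122 up, 194 down), or 65 without background correction. The siPRKDC and siNeg values of a gene did not overlap for 48.2% of genes, where chance gives 10%.

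Among the 10 largest falls in TC32, CRYAB, a small heat shock protein, fell 7.33-fold (log2 change -2.87, SE 0.09, adjusted p = 4.88e-16). ANXA1 fell 7.28-fold and the G-protein regulator RGS4 fell 6.91-fold, to a level detected on 1 of 3 siPRKDC arrays. The retinoid enzyme genes DHRS3 and ALDH1A1 fell 7.25-fold and 5.74-fold. COL3A1, which encodes a fibrillar collagen, fell 5.59-fold, and TFPI, a coagulation inhibitor, fell 4.99-fold. NWD1 fell 4.82-fold, to a level detected on 2 of 3 arrays. The long non-coding RNA DIRC3 fell at least 5.67-fold and AADACL4 at least 5.87-fold, since neither was detected on any siPRKDC array. Among protein-coding genes, the largest rises were in the histone gene H2BC5 (5.13-fold, from a level detected on 1 of 3 siNeg arrays), the quinone reductase gene NQO1 (3.84-fold), the transcription factor gene KLF2 (3.75-fold) and DPYSL3 (3.56-fold, detected on 2 of 3 siNeg arrays). A second H2BC5 probe rose less, by 1.18 on the log2 scale against 2.36.

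The other 6 of the 10 largest rises in TC32 were ribosomal and spliceosomal RNAs. RNA28SN5 rose 8.37-fold (log2 change 3.07, SE 0.17, adjusted p = 3.15e-12), and by 1.69 on the log2 scale with its other probe. RNA5S9 rose by 2.28 and RNU4-2 by a fitted 2.17, from a level detected on 1 of 3 siNeg arrays. The U1 genes RNVU1-18, RNU1-3 and RNVU1-7 rose by 2.43, 2.38 and 2.28, but they are near-identical copies of 1 family, as is RNU1-1. Among 12 ribosomal and spliceosomal RNA genes, 11 rose in TC32 and the median log2 change was 1.89, from 0.19 for RNU6-1 (adjusted p = 0.127) to 3.07. In HCT116, 5 of the 12 rose and the median was 0.23. With the 4 U1 copies merged, 8 of 9 families rose in TC32 (median 1.39). In HCT116, 2 of the 9 rose in every copy and U1 in 3 of 4 copies (median 0.18). Most of these RNAs carry no poly(A) tail, and their signal is also a common sign of RNA quality and yield. The siPRKDC arrays of TC32 detected 15396 to 16216 probes and its siNeg arrays 16324 to 16603.

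Of the gene lists, 7 of 18 passed in TC32. Targets known to be repressed by EWS-FLI1 fell, 12 of 19 down and 1 up, with a median log2 change of -0.44 (adjusted p = 1.95e-04). Besides COL3A1, they included the contractile and matrix genes CCN2 (-1.37), ACTA2 (-1.14) and, on 2 of its 3 probes, CALD1 (-0.96). ZYX rose by 0.44. Genes of the ATF4 and unfolded protein response fell, 9 of 15 down and 1 up, with a median of -0.67 (adjusted p = 1.95e-04), and 10 were down when adjusted over the list alone. The amino acid synthesis genes CTH (-1.44), ASNS (-1.07) and PHGDH (-0.84) fell, as did TRIB3 (-1.38) and ATF4 itself (-0.67). The endoplasmic reticulum chaperone gene HSPA5 rose by 0.38. Ribosome biogenesis genes rose, 10 of 14 with none down (median 0.33, adjusted p = 0.00131), and 11 when adjusted over the list alone. BOP1 (0.95), NOP56 (0.94), RRS1 (0.72) and RRP12 (0.64) moved most. Polyadenylated histone transcripts rose, 5 of 6 (median 0.66, adjusted p = 6.20e-04), and 6 when adjusted over the list alone. With detection p below 0.01 required on all 12 arrays, 4 of them were measured and the list was not called (adjusted p = 0.0743, the highest of any alternative). After H2BC5, the rises were in H2AC20 (0.74), H2BC12 (0.58, on 1 of its 2 probes) and H2AC6, which was not detected on any siNeg array.

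The other 3 lists that passed in TC32 rested on the preset correlation between genes. Genes of G2/M and mitosis fell, 13 of 22 down and 2 up (adjusted p = 0.0209, but adjusted p = 0.0583 with an estimated correlation). AURKA (-0.93), AURKB (-0.66) and CCNB2 (-0.59) fell, whereas CENPF rose by 0.47 and BIRC5 by 0.58 on 1 of its 2 probes. Interferon response genes fell, 7 of 14 down and 2 up (adjusted p = 0.0386, but adjusted p = 0.0793 with an estimated correlation), led by IFITM1 (-1.96) and ISG15 (-0.91), while IFIT1 (-0.66) fell to a level detected on 1 of 3 siPRKDC arrays. Their call was also lost without siNeg replicate 1 (adjusted p = 0.0700), siPRKDC replicate 1 (0.0885) or siPRKDC replicate 2 (0.145), within a range over all alternatives that reached 0.716. Immediate early and MAPK response genes rose, 7 of 18 up and 1 down (adjusted p = 0.0386, but adjusted p = 0.0793 with an estimated correlation), with IER3 (1.30), DUSP6 (1.04) and EGR1 (0.63) up and FOS (-0.84) down. Without siPRKDC replicate 1, their adjusted p was 0.0938, the highest of any alternative.

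The remaining lists did not shift as groups in TC32, though single members changed. EWS-FLI1 activated targets went both ways, 5 up and 5 down of 22 (adjusted p = 0.980), with CCK (1.28) and XG (at least 1.39-fold) up and PAPPA (-0.79) and ITM2A (-0.54) down. Ewing sarcoma, neural and mesenchymal markers did likewise, 8 up and 5 down of 18 (adjusted p = 0.217), with CDH11 (1.10), TUBB3 (0.73) and NCAM1 (0.70) up and HOXD13 (-0.91) down. Of the p53 targets, 3 of 18 rose and 3 fell (adjusted p = 0.788). CDKN1A rose by 1.36 and BAX by 1.05, while CCNG1 fell by 0.63. ZMAT3 fell by 0.41 on its brightest probe, while another of its probes rose by 0.39. Hypoxia and glycolysis genes split, 3 up and 4 down of 13 (adjusted p = 0.860), with VEGFA (0.79, on 1 of its 2 probes) and SLC2A1 (0.75) up and ALDOC (-1.45) and ADM (-0.76) down.

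The DNA repair lists were not called in TC32. Among 8 non-homologous end joining genes, the pathway in which PRKDC acts, APTX (0.50) and PAXX (0.30) rose and TDP1 fell by 0.53 on its brightest probe alone (list adjusted p = 0.644). Homologous recombination and Fanconi anaemia genes had 1 of 13 up and 4 down (adjusted p = 0.980). Kinases related to PRKDC and checkpoint genes had 4 of 14 up and 1 down (adjusted p = 0.456), with TRRAP (0.45) and SMG1 (0.41) up and MDC1 (-0.48) down. DNA replication and S phase genes had 5 of 20 up and 2 down (adjusted p = 0.368), with POLA1 (0.72) and GINS2 (0.53) up. Cholesterol synthesis genes had 3 of 11 up and 1 down (adjusted p = 0.604), or 4 and 2 when adjusted over the list alone, with SQLE up by 0.46 and HMGCS1 down (-0.47). Of 4 NF-kB genes, NFKBIA rose by 0.74 (list adjusted p = 0.788). Epithelial and colon markers had 1 of 12 up and 1 down (adjusted p = 0.940), the fall being CEACAM6 (-1.52). The rise was KRT18 (0.35), detected on 1 of 3 siNeg arrays, which another of its probes contradicted (-0.63). It was lost without siNeg replicate 1 (adjusted p = 0.194) or replicate 2 (0.137), without siPRKDC replicate 1 (0.102) or replicate 3 (0.138), and in other alternatives up to 0.343. Adjusted over the list alone, no epithelial marker rose and 9 Ewing sarcoma, neural and mesenchymal markers did. The median and mean had opposite signs for the EWS-FLI1 activated (-0.05 and 0.01), hypoxia (0.01 and -0.06) and NF-kB (-0.06 and 0.12) lists, and the recombination list had a median of 0.06 with a test pointing down.

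In HCT116, the comparison asks which changes the same siRNA brought in a line that is not Ewing sarcoma. The lists of DNA replication and S phase, of G2/M and mitosis, and of homologous recombination and Fanconi anaemia fell there as groups. The response was smaller than in TC32, with 1948 genes changed (956 up, 992 down) and 40 changed at least 2-fold (16 up, 24 down), or 6 without background correction. The siPRKDC and siNeg values of a gene did not overlap for 35.2% of genes.

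After PRKDC, the largest falls in HCT116 were in ATP1B3, a sodium pump subunit gene (3.52-fold), the ubiquitin-conjugating enzyme gene UBE2E3 (3.35-fold) and CMTM6 (3.02-fold). The cyclin-dependent kinase genes CDK2 and CDK6 fell 2.83-fold and 2.81-fold. CCDC167 (-1.48), ANXA7 (-1.32), DCAKD (-1.27) and NAP1L1 (-1.26) followed on the log2 scale, NAP1L1 on its brighter probe alone. The largest rises were in PRF1 (3.22-fold), the carboxypeptidase gene CPA4 (3.10-fold), TNFRSF6B (3.02-fold), the keratin gene KRT80 (2.99-fold) and CALB2 (2.88-fold). HAS3 (2.81-fold) and PDLIM7 (2.49-fold) rose on 1 of their 2 probes, and COL13A1 (2.66-fold), the AP-1 gene JUN (2.46-fold) and TCN1 (2.39-fold, detected on 2 of 3 siNeg arrays) completed the group.

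In HCT116, 3 of 18 lists passed, all downward and all also with an estimated correlation. DNA replication and S phase genes fell, 16 of 20 with none up (median -0.47, adjusted p = 7.79e-12), and 17 when adjusted over the list alone. RRM2 fell most (-1.17), followed by MCM7 (-0.67, on 2 of its 3 probes), CDC45 (-0.63) and CHAF1B (-0.58). Genes of G2/M and mitosis fell, 13 of 22 with none up (median -0.31, adjusted p = 6.15e-10), and 17 when adjusted over the list alone. NUSAP1 (-0.62) and PTTG1 (-0.53) fell, as did CDK1 (-0.77) and BIRC5 (-0.74), each on 1 of its 2 probes. Homologous recombination and Fanconi anaemia genes fell, 6 of 13 down and 1 up (median -0.30, adjusted p = 2.88e-04), and 8 when adjusted over the list alone. EXO1 (-0.82), BLM (-0.77) and FANCG (-0.65) fell, as did BRCA1 (-0.48) on 1 of its 2 probes, while NBN rose by 0.33. The NBN rise was lost without siNeg replicate 2 (adjusted p = 0.0857, the highest of any alternative) or siPRKDC replicate 2 (0.0550).

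**Figure D2:**
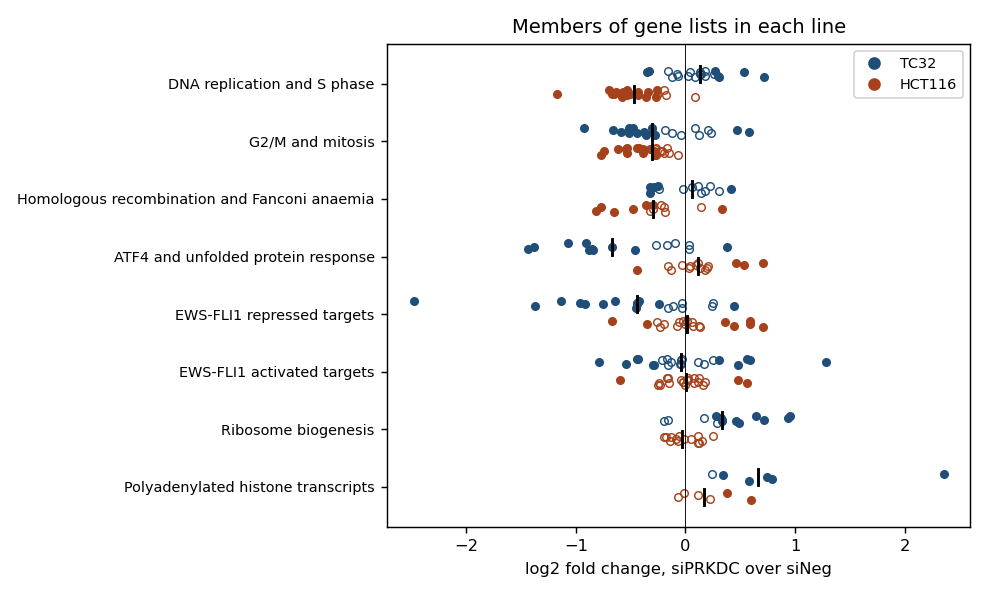
Log2 change with siPRKDC of the measured members of selected gene lists, in TC32 and HCT116. Drawn are DNA replication and S phase, G2/M and mitosis, and homologous recombination and Fanconi anaemia. Also drawn are the ATF4 and unfolded protein response, EWS-FLI1 repressed and activated targets, ribosome biogenesis and polyadenylated histone transcripts. The other lists are not drawn. DNA replication and S phase genes had a median of -0.47 in HCT116, and ATF4 and unfolded protein response genes a median of -0.67 in TC32.

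Single members of the other lists changed in HCT116. Of 18 immediate early genes, 4 rose and 3 fell (adjusted p = 0.735), with JUN (1.30) and DUSP5 (0.79) up and EGR1 (-0.84) down. Of 18 p53 targets, GDF15 rose (0.74), while CCNG1 (-0.73) and, on 1 of its 2 probes, TP53INP1 (-0.55) fell (adjusted p = 0.965). ATF4 list genes had 3 of 15 up and 1 down (adjusted p = 0.176), with PSAT1 (0.71), ATF3 (0.53) and ASNS (0.46, on 1 of its 2 probes) up and XBP1 (-0.44) down. EWS-FLI1 repressed targets had 5 of 19 up and 2 down (adjusted p = 0.616), with THBS1 (0.71), CCN1 (0.59) and TPM1 (0.59, on 2 of its 3 probes) up and PHLDA1 (-0.67) down, though another PHLDA1 probe moved the opposite way. EWS-FLI1 activated targets had CCND1 (0.56) and PTPN13 (0.48) up and ID2 (-0.60) down (adjusted p = 0.965). Epithelial and colon markers had 4 of 12 up and 1 down (adjusted p = 0.176, or 0.0471 without the filter on dim probes), led by CDH1 (0.63). Hypoxia genes HK2, on 1 of its 2 probes, and NDRG1 each rose by 0.74 and ADM fell (-0.30), with 13 measured (adjusted p = 0.963). The ADM fall was lost without siNeg replicate 1 (adjusted p = 0.0760), siNeg replicate 2 (0.0574) or siPRKDC replicate 3 (0.0807, the highest of any alternative). Of 4 NF-kB genes, CXCL8 rose (0.87) and NFKBIA fell (-0.44; list adjusted p = 0.963).

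Fewer genes moved in the rest of the lists in HCT116. Of 14 interferon genes 1 rose and 2 fell, among them IFIT1 (-0.62; list adjusted p = 0.662). Of 14 kinase and checkpoint genes, MDC1 (-0.37) and ATM (-0.36) fell (adjusted p = 0.176). The ATM fall rested on 1 of its 2 probes and was lost without siNeg replicate 1 (adjusted p = 0.0820) or siPRKDC replicate 1 (0.136), within a range over all alternatives that reached 0.207. Of 11 cholesterol genes, INSIG1 rose by 0.41 (list adjusted p = 0.614). Of 6 polyadenylated histone transcripts, H2BC12 rose by 0.60 and H2BC5 by 0.38 (list adjusted p = 0.176). The H2BC5 rise was lost without siNeg replicate 2 (adjusted p = 0.0541) or siPRKDC replicate 2 (0.0536). No member was called among 8 non-homologous end joining genes (adjusted p = 0.616), 14 ribosome biogenesis genes (adjusted p = 0.965) or 18 Ewing sarcoma, neural and mesenchymal markers (adjusted p = 0.965). Adjusted over the list alone, 6 epithelial markers rose and 2 fell, 3 EWS-FLI1 repressed targets fell, 2 p53 targets rose and 4 immediate early genes fell. The median and mean had opposite signs for the hypoxia (-0.02 and 0.06) and NF-kB (-0.01 and 0.10) lists.

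Whether the effect of siPRKDC differed between the lines was tested directly. As groups, the ATF4 response, EWS-FLI1 repressed targets, DNA replication genes and ribosome biogenesis genes responded differently in the lines. The effect differed for 3320 genes, more positive in TC32 for 1707 and more negative for 1613. Of these, 177 were not detected on any HCT116 array and 114 on no TC32 array, and 3029 were detected in both lines.

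By fitted value, most of the 10 largest differences were in genes that fell in TC32. DHRS3 was detected in both lines, and its change was more negative in TC32 (log2 difference -3.17, SE 0.19, adjusted p = 8.09e-11). CRYAB, AADACL4, DIRC3 and COL3A1 were not well above background on any HCT116 array, where no fall could have been seen, so no size is given for their differences. ALDH1A1 (-2.65) was detected on 1 of 6 HCT116 arrays and RGS4 (-2.79) on 3 of 6, which left little room for a fall there. PKIB (-2.58) moved in opposite directions: its mean log2 intensity went from 6.95 to 5.36 in TC32 and from 4.88 to 5.88 in HCT116. IL1RAPL1 (-2.36) fell in TC32 from 7.03 to 4.79, but was near background in HCT116 (4.64 with siNeg and 4.75 with siPRKDC), which also left little room for a fall. RNA28SN5 was the 1 gene of the 10 with the more positive change in TC32 (2.38).

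Of the lists, 6 differed between the lines. DNA replication and S phase genes changed more positively in TC32 (median difference 0.53, 14 of 20 and 15 when adjusted over the list alone, none the other way, adjusted p = 1.29e-06), led by RRM2 (1.43), POLA1 (1.08) and GINS2 (0.95). ATF4 list genes changed more negatively (median difference -0.81, 10 of 15, 1 the other way, adjusted p = 8.21e-06), led by ASNS (-1.54), CTH (-1.48) and TRIB3 (-1.42). EWS-FLI1 repressed targets also changed more negatively (median difference -0.58, 11 of 19, none the other way, adjusted p = 2.81e-05), among them CCN2 (-1.49) and TPM1 (-1.24). Ribosome biogenesis genes changed more positively (6 of 14 and 10 when adjusted over the list alone, adjusted p = 0.00308), led by NOP56 (1.07). These 4 calls held with an estimated correlation. Polyadenylated histone transcripts (adjusted p = 0.0123, but adjusted p = 0.0614 with an estimated correlation) and homologous recombination genes (adjusted p = 0.0394, but adjusted p = 0.0913 with an estimated correlation) also changed more positively in TC32. The histone call was also lost in 4 other alternatives, up to 0.362. The recombination call was lost without TC32 siPRKDC replicate 2 (adjusted p = 0.0547), HCT116 siNeg replicate 2 (0.0513) or HCT116 siNeg replicate 3 (0.0532), within a range over all alternatives that reached 0.210. The other 12 lists did not differ as groups, with adjusted p from 0.0812 to 0.969. The lowest, for kinase and checkpoint genes, was 0.0246 without the filter on dim probes. The median and mean difference had opposite signs for EWS-FLI1 activated targets (-0.05 and 0.01), cholesterol genes (-0.01 and 0.02) and NF-kB genes (-0.06 and 0.02). The G2/M list did not differ between the lines as a group (adjusted p = 0.348), although BIRC5 (1.32) and CDK1 (0.73) did. Single genes of other lists differed as well, among them CDKN1A (1.61), EGR1 (1.47), IER3 (1.47), NFKBIA (1.19) and BAX (1.05), which were more positive in TC32. ALDOC (-1.29), ISG15 (-1.09) and JUN (-0.92) were more negative in TC32. So were the fitted changes of IFITM1, detected on 3 of 6 HCT116 arrays, of CEACAM6, detected on none of them, and of CXCL8 and GDF15, near background in TC32, and no size is given for these.

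The changes common to both lines were then compared, since they followed the same siRNA in different cells. Few genes moved strongly in both, and those that did mostly fell. Of 961 genes called in both lines, 670 changed in the same direction. There were 369 shared falls where 208 would be drawn from independent lists (odds ratio 2.48, Fisher's exact p = 3.05e-35), and 301 shared rises against 208 (odds ratio 1.75, Fisher's exact p = 2.45e-13). Fisher's test takes genes as independent, which they are not, so these p-values do not measure how far the sharing would recur in new samples. Another 143 fell in TC32 and rose in HCT116, and 148 did the reverse. Across all genes, which are not independent replicates, the log2 changes correlated weakly (Pearson r 0.17, Spearman rho 0.13).

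At least 2-fold changes in both lines in the same direction were seen for 12 genes, of which 11 fell, PRKDC among them. UBE2E3 fell by 2.07 on the log2 scale in TC32 and by 1.74 in HCT116. Another UBE2E3 probe also fell (-1.27 and -1.53), while a dim one rose in HCT116 (0.44). CMTM6 (-1.49 in TC32 and -1.59 in HCT116) and CCDC167 (-1.40 and -1.48) fell in both, and ATP1B3 fell further in HCT116 (-1.20 and -1.82). The proteasome subunit gene PSMB3 (-1.18 and -1.06), WDFY1 (-1.21 and -1.05) and DEPDC1B (-1.08 and -1.14) fell, as did the deacylase gene SIRT5 (-1.63 and -1.06), whose next probe fell less (-0.71 and -0.52). The nucleosome assembly gene NAP1L1 (-1.02 and -1.26) and CNN2 (-1.02 and -1.16) lay beyond the first 10 shared changes. CNN2 was named after its values were seen, and NAP1L1 is among the 10 largest falls in HCT116. CEMIP2, which encodes a hyaluronidase, was the 1 shared rise (1.19 and 1.12). Their number was 1 without background correction and 7 with the mean of a gene's probes.

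**Figure D3:**
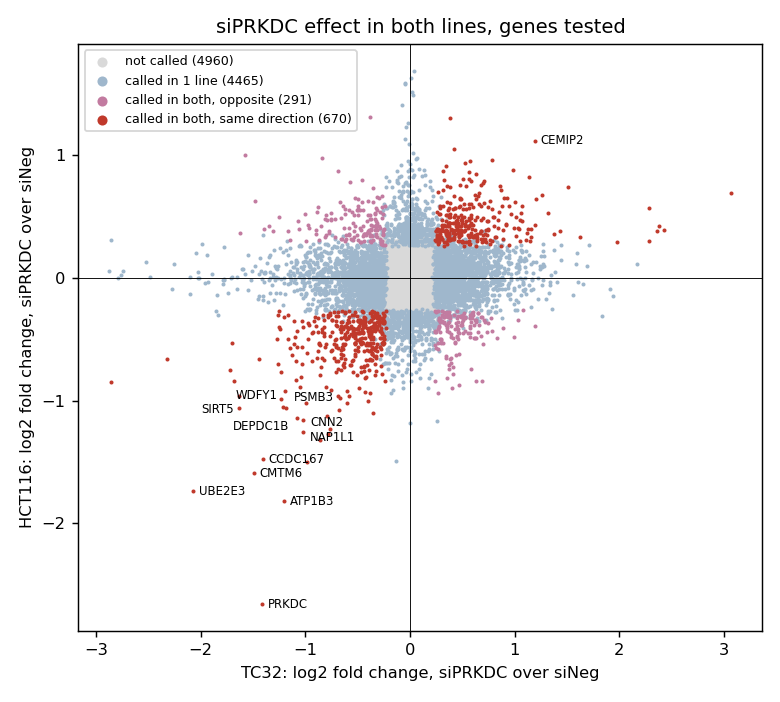
Log2 change with siPRKDC in TC32 against that in HCT116, with each point 1 of 10386 genes. The 12 genes changed at least 2-fold in the same direction in both lines comprise 11 falls and 1 rise, and r across genes was 0.17.

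The lines under siNeg were compared as a background for these effects. As groups, EWS-FLI1 activated targets and Ewing sarcoma, neural and mesenchymal markers were higher in TC32, and epithelial and colon markers were lower. The lines were also grown in different media (RPMI-1640 and DMEM). Of 10386 genes, 6877 differed, 3125 higher in TC32 and 3752 lower, with 1650 at least 2-fold apart. ITM2A was at least 124-fold higher in TC32, TUBB2B at least 94.9-fold, IGFBP5 at least 92.3-fold, PRAC1 at least 87.0-fold and GRP at least 81.1-fold. The metallothionein gene MT1E, detected on 2 of 3 TC32 arrays, was lower there by a fitted 114-fold, KRT19 at least 73.4-fold, CMTM7 49.1-fold, SPINT2 at least 45.7-fold and EPCAM at least 45.1-fold. EWSR1 was lower in TC32 (-0.86, adjusted p = 4.26e-08) and FLI1 higher (0.48, adjusted p = 0.00374), FLI1 being detected on 1 of 3 HCT116 arrays. PRKDC was lower in TC32 (-0.55, adjusted p = 0.00147), but not with the mean of its probes (-0.08, adjusted p = 0.430).

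Of the fixed lists, EWS-FLI1 activated targets were higher in TC32 (18 of 22, adjusted p = 1.74e-08), with NKX2-2 at least 36.4-fold and PRKCB at least 34.6-fold higher. Ewing sarcoma, neural and mesenchymal markers were higher (16 of 18, adjusted p = 4.59e-07), among them VIM (4.86), UCHL1 (at least 17.6-fold) and BASP1, which was detected on 1 of 3 HCT116 arrays. Epithelial and colon markers were lower (10 of 12, adjusted p = 2.71e-05), as KRT8 was at least 25.9-fold, but CEACAM6 was at least 28.6-fold higher. Immediate early genes were lower (16 of 18, adjusted p = 2.41e-04), IER3 most (-4.94), whereas FOS was higher (2.63). G2/M genes were higher (15 of 22, adjusted p = 0.00482), TOP2A most (1.79), and p53 targets lower (11 of 18, adjusted p = 0.0113), among them CDKN1A (-3.93) and GDF15, which was detected on 1 of 3 TC32 arrays. The p53 call was lost with the stricter detection filter (adjusted p = 0.0732, the highest of any alternative). Hypoxia genes were lower, 13 of 13, including SLC2A1 (-3.83; list adjusted p = 2.71e-05, but adjusted p = 0.0651 with an estimated correlation). Cholesterol genes were higher, 8 of 11 and 9 when adjusted over the list alone (adjusted p = 0.0108), and homologous recombination genes higher, 7 of 13 (adjusted p = 0.0288), but both lost the call (adjusted p = 0.0651 with an estimated correlation). Polyadenylated histone transcripts were lower, 5 of 6 (adjusted p = 0.0226), as were NF-kB genes, 4 of 4 (adjusted p = 0.0252), and these calls were lost too (adjusted p = 0.0651 with an estimated correlation). The histone call was also lost without the filter on dim probes (adjusted p = 0.0674) and with the stricter one (0.0732). The NF-kB call was lost without TC32 siNeg replicate 2 (adjusted p = 0.0958), within a range over all alternatives that reached 0.191.

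The other lists were not called between the lines as groups, though several were called in some alternatives. EWS-FLI1 repressed targets were split, 10 higher in TC32 and 8 lower (adjusted p = 0.564, median 0.32 and mean -0.10), with COL3A1 at least 23.3-fold higher and PHLDA1 lower (-5.34). ATF4 list genes had 9 of 15 higher and 4 lower (adjusted p = 0.107), with DDIT4 lower (-3.02). DNA replication genes had 11 of 20 lower and 4 higher (adjusted p = 0.131), with CCNE1 lower (-1.96). They were called as lower with median scaling (adjusted p = 0.0489), the authors' values (0.0412) and no filter on dim probes (0.0468). Without that filter, ATF4 list genes were called as higher (0.0468). With the stricter detection filter, EWS-FLI1 repressed targets were called as higher (0.0123, on 9 genes) and interferon genes as lower (0.0283, on 3 genes). Ribosome biogenesis genes had 7 of 14 lower and 1 higher (adjusted p = 0.0712), with BOP1 lower (-1.47). They were called without TC32 siNeg replicate 2 (adjusted p = 0.0453) and in 4 other alternatives, down to 0.0174. Interferon genes (adjusted p = 0.484), non-homologous end joining genes (adjusted p = 0.703) and kinase and checkpoint genes (adjusted p = 0.670) went both ways, with IFITM1 (2.95, detected on 2 of 3 HCT116 arrays) and TDP1 (1.68) higher and XRCC6 lower (-1.04).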

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

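The tests of why more genes changed in TC32 than in HCT116 were chosen only after the result was seen. The splits of the samples were planned.

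The results listed here first differed between the lines in their response to siPRKDC by the test of that difference. They were the 3320 genes of that comparison, with PRKDC (1.25) and EWSR1 (0.69) among them. Among the 10 genes with the largest fitted differences, TC32 minus HCT116 on the log2 scale, were DHRS3 (-3.17), RGS4 (-2.79), ALDH1A1 (-2.65), PKIB (-2.58), RNA28SN5 (2.38) and IL1RAPL1 (-2.36). RGS4 was detected on 3 and ALDH1A1 on 1 of 6 HCT116 arrays, so their fitted values depend on the floor. The other 4 were CRYAB, AADACL4, DIRC3 and COL3A1, which were not well above background on any HCT116 array, so neither the size of their differences nor their place among the 10 was measured.

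Of the gene lists, the mean change was more negative in TC32 for ATF4 and unfolded protein response genes (-0.70) and EWS-FLI1 repressed targets (-0.57). It was more positive for polyadenylated histone transcripts (0.63), DNA replication and S phase (0.57), ribosome biogenesis (0.40), and homologous recombination and Fanconi anaemia (0.32). The histone and recombination calls were lost with an estimated correlation.

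Signal also changed in probes outside the gene comparisons. Of 3159 kept probes without 1 gene, 955 changed with siPRKDC in TC32 (30.2%) and 308 in HCT116 (9.75%). They were tested with limma among all 16555 kept probes, and p-values were adjusted over all of these. As with the named genes, more changed in TC32. Groups of 3 samples were not tested for single samples far from the rest.

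Other splits of the samples were counted beside each comparison. In TC32, 1 of the 10 splits of the 6 samples into 3 and 3 gave as many genes, the real one (4439 genes, highest other 0). In HCT116 it was 1 of 10 (1948 genes, highest other 0), and between the lines under siNeg 1 of 10 (6877 genes, highest other 0). With 10 splits, no share under 0.05 can be reached. For the difference between the lines, 2 of 100 drawn splits gave as many genes as the real 3320. The other of the 2 gave 4024 genes and exchanges both treatment labels in 1 line only, which turns the difference of the effects into their sum. For genes changed in the same direction in both lines, 1 of 100 drawn splits gave as many as the real 670 (highest other 291). No other split within a line called a gene, since mixing the treatments puts their effect into the residual spread. Splits that mix them in both lines (80 of the 99 others) therefore gave 0 genes by both counts, so the splits say neither that the lines differ nor that they share changes.

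More genes changed in TC32 than in HCT116, and several technical sources could have produced this. The ratio of the median replicate SD in TC32 to that in HCT116 was 1.10. The counts come from 1 estimate of the spread shared by the 4 groups, and the median SD was not smaller in TC32 (0.125 against 0.114 in HCT116). A smaller spread between TC32 replicates is therefore argued against as the source. A larger fall of PRKDC in TC32 is argued against by its brightest probe, whose change was 1.25 more positive in TC32, but by that probe alone: the mean of its probes gave 0.33 (adjusted p = 0.0596), and the 2 dimmer ones, near background after siPRKDC, fell slightly more in TC32 (by 0.86 and by 0.92) than in HCT116 (by 0.78 and by 0.73). Normalizing the lines together is argued against by the authors' values, normalized within each line, which gave 1.79 times as many genes in TC32, against 2.08 with the lines normalized together and, as in those values, no background correction (2.28 with it). A difference in RNA quality between the TC32 groups stays open, as the siPRKDC arrays there had a median rise of 1.89 in ribosomal and spliceosomal RNA genes (1.39 by family) and fewer detected probes (15396 to 16216 against 16324 to 16603), and so do untested differences in the cells' need for PRKDC, media, handling and transfection.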

How the results depend on the processing

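The analysis without non-polyadenylated RNA probes was chosen only after the results were seen, and all other alternatives were planned. The cause was not tested for any change given here unless stated.

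The number of genes changed in TC32 (4439) stayed within 1.5 times its value in every alternative, from 3272 to 4541, and 3 or 4 lists were called in HCT116. Leaving out 1 sample gave 3994 to 4190 genes in TC32, 1464 to 1538 in HCT116, 2957 to 3309 for the difference, 6493 to 6726 under siNeg and 539 to 655 changed in the same direction. At least 2-fold, it gave 305 to 343 in TC32, 40 to 46 in HCT116 and 11 to 13 in both. PRKDC fell and was called in every alternative, with a change as small as -0.71 in TC32 with the authors' values and -1.38 in HCT116 without background correction. Leaving out 1 sample, the PRKDC change ran from -1.59 to -1.27 in TC32 and from -2.75 to -2.57 in HCT116, and the lists called from 5 to 7 in TC32 and from 3 to 3 in HCT116.

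Counts at least 2-fold in TC32, HCT116 and both (316, 40 and 12) fell where a larger offset was added or background stayed in the signal, either of which compresses the folds. They were 92, 12 and 2 with an offset of 50, 65, 6 and 1 without background correction, and 63, 6 and 1 with the authors' values. The stricter detection filter, which tests fewer genes, gave 203 in TC32, 22 in HCT116 and 4398 genes under siNeg. The mean of a gene's probes left 7 genes changed at least 2-fold in both. The stricter threshold of 0.01 gave 1085 genes in HCT116, 2083 for the difference, 378 in the same direction and 4 lists in TC32, and the estimated correlation also gave 4 lists.

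Of 333 called results for named genes, 36 lost the call in at least 1 alternative. The other 297 kept their call and direction in every alternative that measured the gene. The stricter detection filter measured fewer of these genes. With the mean of a gene's probes, ZMAT3 (0.03) and KRT18 (-0.14) reversed in TC32, and so did the differences of TDP1 (0.02) and ZMAT3 (0.05), because their probes moved in opposite directions. The share of called genes that were higher moved by more than 10 points for the difference with median scaling (40.5% against 51.4%) under siNeg with the authors' values (30.7% against 45.4%), and at least 2-fold in HCT116 with the authors' values and without background correction (16.7% against 40.0%). The median change of all genes never exceeded 0.10 in size. The replicate block gave 4541 genes in TC32, 2010 in HCT116 and 695 in the same direction. Deviations of like-numbered samples correlated weakly, at r from 0.00 to 0.11, against -0.07 to 0.03 for the other pairs, so a weak pairing is not excluded. Without non-polyadenylated RNA probes, 4378 genes changed in TC32 and 1927 in HCT116. An array position block was not run, since the headers do not give positions, and lines fitted alone give no difference between lines. Signal over background limits genes near the floor: a fold is a lower bound where no array of a group detected the probe, and the fitted size depends on the floor where only some did.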

Other observations

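The grouping of structural RNAs, the tests on them and the tests on the shared falls were all chosen only after the results were seen.

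The structural RNAs of TC32 did not move as 1 class. Among 117 other structural RNA genes, 44 rose and 6 fell (median log2 change 0.18), against 11 and 7 in HCT116 (median 0.00). RN7SK rose by 1.44, the U3 gene SNORD3A by 1.15 and the RNase P gene RPPH1 by 0.88. The Y RNA gene RNY4 fell (-0.90). RN7SL1, the signal recognition particle RNA, was not called (-0.07, adjusted p = 0.597). However, it lay near the top of the intensity range with siNeg, which left little room for a rise. Most of the 117 genes lay near background with siNeg, so a missing change in these says little. That the class was mixed therefore rests on the called changes in both directions. Within the ribosomal and spliceosomal group, RNA18SN5 rose by 1.39, while the U6 gene RNU6-1 was not called (0.19, adjusted p = 0.127). RNU6-1 was called with an offset of 50 (adjusted p = 0.0360), without background correction (0.0375) and with the authors' values (0.0371).

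The rise of ribosomal and spliceosomal RNA signal in TC32 may be technical or may follow from PRKDC loss. Background correction or normalization is argued against by the median log2 change of the 12 genes, which was 1.09 or more under 5 other normalizations, or 0.88 or more with the U1 copies as 1 family. As to an effect of 1 or 2 odd arrays, 11 of the 12 genes, and 8 of 9 families, had every siPRKDC value above every siNeg value. Among all genes in TC32, the values of 48.2% did not overlap, in either direction. The RNAs among the largest rises were named only if their values did not overlap, so for them this count was fixed in advance. The rest of the 12 were taken by gene name without that condition. All but 1 of the rest also had every siPRKDC value above every siNeg value. For these genes this argues against 1 or 2 odd arrays, though several lay near background with siNeg. A higher yield of all RNAs without a poly(A) tail cannot be told apart. The 5 other structural RNA genes well above background had a median of 0.62 with a bootstrap interval from -0.15 to 1.44. RN7SL1, with little room for a rise, was among them. A difference in RNA quality between the TC32 groups was not measured here, and an effect of PRKDC loss on these RNAs also stays open.

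The strongest changes shared by both lines were falls, and direct silencing of other transcripts by the siRNA is a candidate explanation. Among the weaker shared changes, 358 fell and 300 rose, 54.4% falls, against 48.0% of genes called in 1 line alone (odds ratio 1.30, 95% CI 1.10 to 1.53, Fisher's exact p = 0.00200), but the excess of shared falls was already known, so this does not speak for silencing. The test also takes genes as independent, which they are not. Background correction or normalization is argued against, since falls made up at least 17 of the 20 largest shared changes under 5 other normalizations, against 18 here. Loss of PRKDC itself could also give shared falls and was not tested against this. The siRNA sequence and the number of siRNAs are not given in the sources used here, so no match to UBE2E3, CMTM6 or the other shared genes was searched.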
